A study of Homo sapiens with 6 samples.

How the data were processed

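The series measured RNA from PC3, an established human prostate cancer cell line, carrying a construct that expresses the transcriptional coactivator PGC1A when doxycycline is given. Per the labels, 3 samples were grown without doxycycline and 3 with it for 2 passages. Total RNA was column-purified, labelled through biotinylated amplified RNA and hybridised to Illumina bead arrays, with 1 array per sample, per the labels' protocols. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Slide and scan date were not analysed here.

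The deposited table of probe intensity holds 47231 probes on a linear scale, from 33.05 to 30152, together with the deposited detection p-value of each probe against the negative controls of its array. The steps between those p-values imply about 770 negative controls per array. These intensity values carry no normalization between arrays that the values show: array medians ranged from 60.03 to 68.04. A table of the authors' processed log2 values was also deposited. The submitters' processing notes name lumi, without a version. Compared with the intensities, that table holds exactly the 17925 probes with a detection p under 0.01 on 1 or more arrays. Its columns equal the log2 intensity without background correction after quantile normalization over those probes, with a largest gap of 0.00035 in the sorted values, and every column correlated with its own array at 0.99994 or more. Each column's median was 7.507. Scanner software and its version are not given in the sources used here.

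Probes were named through the platform's annotation, which lists 13981 of the 17925 processed probes with a gene. Of these, 13977 had 1 gene and 4 had several. The other 3944 were not listed and are unnamed here, and no gene was named from a probe with several. Symbols were updated through Entrez gene numbers in the RefSeq table of assembly GRCh38.p14, where 13970 matched, giving 10756 genes. The files name no genome build, so genomic positions and probe sequences were not analysed here. NDUFA4, now COXFA4, was first lost from the complex I list because its old symbol matched several genes. That match was corrected after COXFA4 had been seen among the called probes, and the list's membership had been fixed before. COXFA4 is now counted as a subunit of cytochrome c oxidase, but it was kept in the list where it had been placed.

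Intensities were background-corrected with the normexp model, using the detection p-values, with an offset of 16, then quantile-normalized and taken to log2 (limma 3.58.1 neqc in R 4.3.3). Probes with a detection p under 0.01 on at least 3 of the 6 arrays were kept, which left 15542 probes. For genes, the probe with the highest mean over all 6 arrays stood for the gene, giving 9841 genes. Of the 2302 genes with several tested probes, 866 had probes that differed in the sign of the change. Groups were compared with limma's lmFit and eBayes, two-sided, and a gene or probe was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. Values are given as mean ± SD of log2 signal over 3 arrays, and changes as log2 fold change with its standard error (SE). A probe below the detection threshold on every array of a group has only a bound there. Its fold is given as "at least", as the brighter group's mean against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own.

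Before the data were examined, 37 gene lists were fixed: mitochondrial and metabolic pathways, stress, growth, adhesion and immune programmes, and markers of other cell types that a culture could hold. The 33 lists with at least 5 tested genes were tested with limma's camera, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera asks whether a list's genes are shifted relative to the other genes. It was repeated with a correlation estimated per list. Limma's fry was run beside it. Its directional p asks whether a list's genes move one way on balance and does not compare them with other genes. The result of 1 tested list is not reported here. Members past the threshold were counted over all genes tested and adjusted over the list alone. Median changes were also placed among 10000 random lists of the same size matched on mean signal.

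Genes were named by a rule fixed at the same time. It took PPARGC1A, PPARGC1B, ESRRA, MYC, TFAM and NRF1, then the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose symbol was no placeholder. From each list it took up to 3 called members with the largest change, or up to 2 members as values where none was called. Genes named outside the rule are said to be chosen after their values were seen.

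The titles give replicate numbers 1 to 3 in each group. Whether they pair the samples was checked from the correlation of deviations from the group means. Arrays with the same number correlated at 0.454, 0.523 and 0.299, and every other pair across the groups correlated below 0. Deviations from a group mean sum to 0, so values above 0 for the same number push the others below 0. The values below 0 are therefore no separate evidence. The numbers were taken to pair the samples for the block, on this limited evidence, since the labels do not say what a number marks. So few arrays can be matched in only a few ways, and such a match can arise by chance. The comparison without the pairing stayed the main one, as fixed beforehand. Values with the replicate number as a block are given where they change a call, or a count by more than 1.5 times.

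The steps were tested on simulated data for this comparison, with 9841 genes and 3 arrays per group. The fit recovered 57% of 100 genes changed by 0.5 log2 and 98% of 100 genes changed by 1 log2, and called 9 unchanged genes. The simulated noise was independent between genes and arrays, without pairing or an array that stands apart, so rates in the real data may differ. The number of arrays limits the precision. Alternatives were no background correction, median scaling, the deposited log2 table, other detection filters, the mean of a gene's probes, the replicate block, array weights, a variance trend with robust eBayes, other thresholds and leaving out each array in turn. Leaving out both arrays numbered 2 was added after the arrays were seen. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.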

Results

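Gene expression was measured on bead arrays in PC3 cells, an established line of human prostate cancer, that carry a doxycycline-inducible PGC1A construct. PGC1A, encoded by PPARGC1A, is a coactivator of transcription known for driving mitochondrial and oxidative metabolism. There were 3 arrays of cells without doxycycline and 3 of cells given doxycycline for 2 passages. The arrays detected 15029, 15201 and 15841 probes without doxycycline and 15479, 15437 and 16012 with it (replicates 1 to 3), with median raw intensities of 66.16, 68.04 and 65.58 against 61.59, 61.45 and 60.03. Doxycycline-treated cells lacking the construct were not analysed here, so the comparison covers doxycycline and induced PGC1A together.

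In a principal component analysis the second component, with 32.9% of the variance, separated the groups. All 3 arrays without doxycycline lay at 3.65 or above, and all 3 with it at -2.96 or below. The first component, with 35.3%, set doxycycline replicate 2 apart at 20.14, where the other 5 arrays lay between -11.15 and 2.89. It also ran in the same replicate order in both groups. Replicates 1 to 3 lay at -11.15, 2.89 and -4.95 without doxycycline and at -7.38, 20.14 and 0.44 with it.

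**Figure D1:**
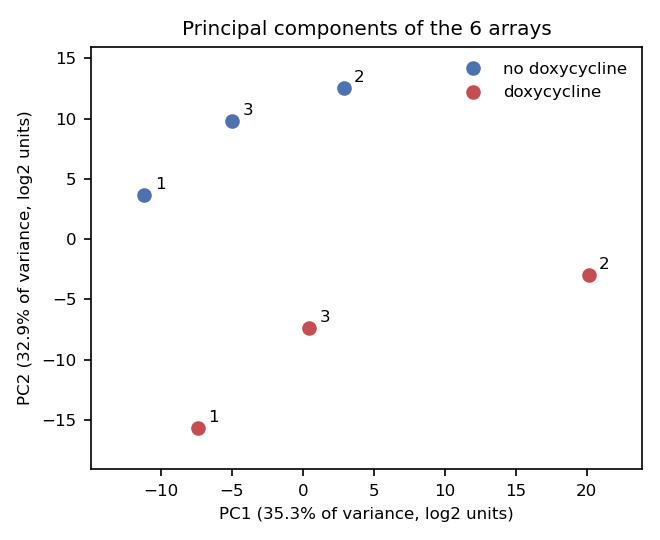
Principal components of the 6 arrays over the genes tested, with the first component on the x axis and the second on the y axis (both in log2 units). Each point is 1 array, coloured by group and numbered by replicate. The groups part along the second component, and doxycycline replicate 2 lies apart at 20.14 on the first. Replicate 2 lies highest on the first component in both groups.

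The design asks what induction of PGC1A does to gene expression in these cells. With doxycycline, ECM1 rose 10.7-fold (5.77-fold without background correction), and MPC1, MPC2 and PDHA1 of pyruvate uptake and oxidation rose in smaller steps, as did single genes of the respiratory chain and of fatty acid oxidation. The lists of these pathways and of the tricarboxylic acid (TCA) cycle passed with a preset correlation between genes, and no list passed with an estimated one. The falls were fewer and included TCN1, CIDEC and TMEM106C. Of 9841 genes tested, 53 passed the threshold, 43 higher and 10 lower with doxycycline (limma, adjusted p under 0.05). In each of the 53 the 3 arrays of one group did not overlap the 3 of the other. Over all genes 2120 (21.5%) showed no such overlap, where chance gives 10%. A measured change of at least 2-fold was found in 8 of the 53, and 6 others have only a bound, since they were not above background in 1 group. With the replicate number as a block 177 genes passed, 133 higher and 44 lower, and these held all 53. The count rested on every array: it was 6, 1 and 1 without no-doxycycline replicates 1, 2 and 3, and 4, 9 and 5 without doxycycline replicates 1, 2 and 3. ECM1 passed in all 6 of those fits, and ATP1B1 and GOT1 in 4 each.

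The induced gene was looked at first. Its probe (ILMN_1750062) lay close to background, at 5.32 ± 0.34 (SD, n = 3) without doxycycline and 5.36 ± 0.33 (SD, n = 3) with it. The log2 fold change was 0.04, with a 95% interval from -0.45 to 0.52 and an adjusted p of 0.951. It was detected on 2 of 3 arrays without doxycycline and on all 3 with it. A probe outside the part of the transcript that a construct carries does not measure the construct, and whether this one lies inside was not analysed here, so it does not check the labels. ESRRA, the orphan nuclear receptor ERR-alpha that partners PGC1A, was at 8.02 ± 0.05 (SD, n = 3) without and 8.52 ± 0.08 (SD, n = 3) with doxycycline, without overlap. Its log2 fold change of 0.50 (SE 0.0816) narrowly missed the threshold (adjusted p = 0.0502) and passed it with the replicate block (adjusted p = 0.037). For PPARGC1B, the related coactivator, the change was 0.20 (adjusted p = 0.579). The mitochondrial transcription factor TFAM was at -0.09 (adjusted p = 0.752) and the nuclear respiratory factor NRF1 at -0.04 (adjusted p = 0.9). PPARGC1B, at 5.09 without and 5.29 with doxycycline, was detected on 2 of 3 arrays in each group. It and NRF1, at 5.38 and 5.34, lay as close to background as PPARGC1A, so a change in them could be missed. MYC was at -0.06 (adjusted p = 0.89) on its brightest probe and at 0.46 (adjusted p = 0.389) on its other probe, so its probes disagreed in sign.

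ECM1, a secreted protein of the extracellular matrix, went from 5.32 ± 0.07 (SD, n = 3) to 8.74 ± 0.36 (SD, n = 3), a log2 fold change of 3.42 (SE 0.166, adjusted p = 0.000409), and its other probe rose by 2.51. Its level without doxycycline lay near background, and the log2 change was 2.53 (5.77-fold, adjusted p = 0.000149) without background correction and 2.53 on the deposited table. ATP1B1, the beta subunit of the sodium pump, rose 3.32-fold (log2 1.73, SE 0.169, adjusted p = 0.0221). MPC1, a subunit of the mitochondrial pyruvate carrier, rose 2.34-fold (log2 1.23, SE 0.143, adjusted p = 0.0291). GOT1, the cytosolic aspartate aminotransferase of the malate-aspartate shuttle, rose 2.06-fold (log2 1.04, SE 0.0871, adjusted p = 0.0127). The other large rises were in TP53INP2, a regulator of autophagy (log2 1.12, adjusted p = 0.0395), the palmitoyltransferase ZDHHC23 (1.04, adjusted p = 0.0438) and the synaptic protein complexin CPLX1 (1.03, adjusted p = 0.0291). The glutathione transferase GSTM1 (0.99, adjusted p = 0.0291), the mitochondrial enzyme CLYBL (0.93, adjusted p = 0.0344) and the cytoskeletal linker GAS2L1 (0.92, adjusted p = 0.0438, and 0.58 without background correction, adjusted p = 0.0241) rose too. CLYBL lost its call for the mean of its probes (0.85, adjusted p = 0.0629), and ZDHHC23 (adjusted p = 0.0515) and GAS2L1 (adjusted p = 0.0557) lost theirs without a detection filter, a setting that ended 23 of the 53 calls. GSTM1 has closely related paralogs, and whether its probe also reads them was not analysed here.

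Among the genes that fell, TCN1, a vitamin B12 binding protein, went from 8.24 ± 0.27 (SD, n = 3) to 7.03 ± 0.26 (SD, n = 3), a log2 fold change of -1.21 (SE 0.171, adjusted p = 0.0388). CIDEC, a lipid droplet protein, fell by 0.95 on the log2 scale (adjusted p = 0.0227), TMEM106C by 0.89 (log2 change -0.89, adjusted p = 0.0291) and the potassium channel KCNJ6 by 0.85 (log2 change -0.85, adjusted p = 0.0327). IFI44L, an interferon-induced gene, fell by 0.75 on its brightest probe (adjusted p = 0.0291), while its other probe was at 0.20 (adjusted p = 0.394). For IFI44L the change was -0.48 without background correction (adjusted p = 0.0199) and -0.28 for the mean of its probes (adjusted p = 0.184). IER5 (-0.55, adjusted p = 0.0395), NUDT11 (-0.50, adjusted p = 0.0438) and the tyrosine kinase LYN (-0.49, adjusted p = 0.0438) fell by less. Without a detection filter these had adjusted p of 0.0515, 0.0557 and 0.0557, and NUDT11 was at -0.34 for the mean of its probes (adjusted p = 0.123). TELO2, a stabiliser of ATM-family kinases, and CEACAM21 were not above background on any array with doxycycline. TELO2 was at least 1.85-fold higher without doxycycline (adjusted p = 0.0291) and CEACAM21 at least 1.34-fold (adjusted p = 0.0438). Without background correction their log2 changes were -0.65 (adjusted p = 0.0186) and -0.31 (adjusted p = 0.0845), and CEACAM21 also lost its call on the deposited table (adjusted p = 0.0859), without a detection filter (0.0564) and with a variance trend (0.074).

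**Figure D2:**
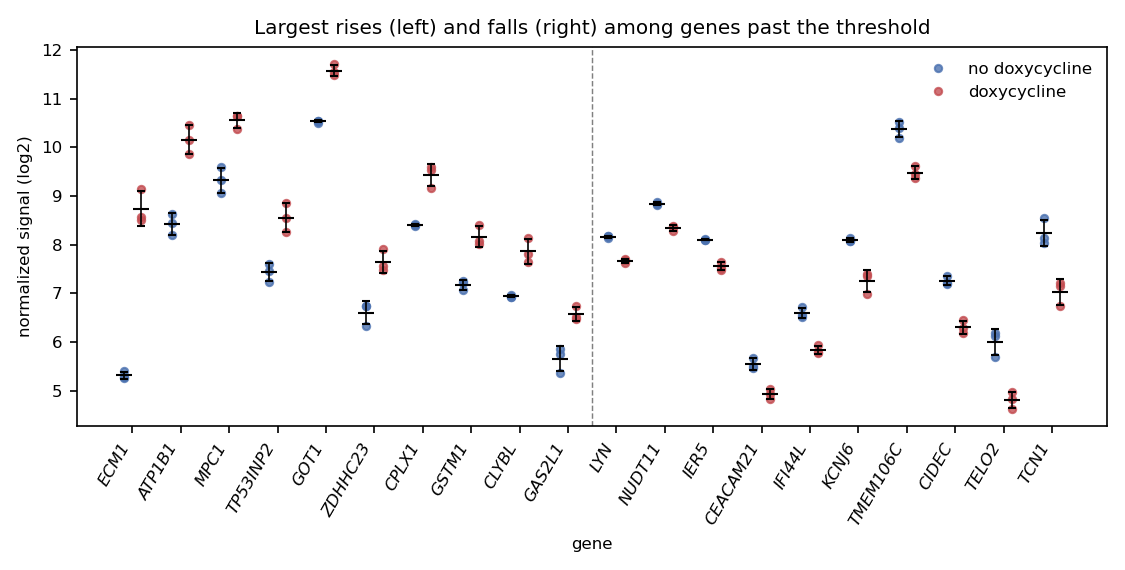
Normalized signal (log2, y axis) of the 10 largest rises and 10 largest falls among genes past the threshold (x axis), with 1 point per array, the horizontal line at the mean and error bars of 1 SD over 3 arrays. The 3 arrays with doxycycline and the 3 without do not overlap for any of these genes, and ECM1 has the largest change, from 5.32 to 8.74; TELO2 and CEACAM21 with doxycycline are not above background.

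Of the 33 lists tested, 15 passed with camera's preset correlation, 12 higher and 3 lower with doxycycline. In the other splits of the 6 arrays into 3 and 3 the same test called from 5 to 13 lists. The count of lists by that test therefore sets the real groups little apart from other splits. Every other split mixes the groups unevenly, so it keeps part of the real difference, and its count is no measure of chance alone. No list passed with an estimated correlation, where 6 had an unadjusted p under 0.05. By fry, 5 passed, all higher: complex I, complex II to IV, ATP synthase, the TCA cycle and fatty acid oxidation.

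The TCA cycle and pyruvate dehydrogenase list had the largest median change, 0.36, with 25 of 26 members above 0 (camera adjusted p = 1.22e-15; adjusted p = 0.148 with an estimated correlation; fry adjusted p = 0.0166). Over all genes tested 3 members rose, and 15 adjusted over the list alone. These 3 were MPC1, its partner subunit MPC2 (0.62, adjusted p = 0.0327) and PDHA1, the catalytic alpha subunit of pyruvate dehydrogenase (0.57, adjusted p = 0.0312). With the replicate block 8 members rose. SDHA, SDHC and SDHD, subunits of complex II, are also in the list of complexes II to IV, so the results of these lists overlap. Fatty acid oxidation and the carnitine shuttle had a median of 0.19 with 23 of 26 members above 0 (camera adjusted p = 1.52e-09; adjusted p = 0.148 with an estimated correlation). Its fry adjusted p was 0.0166, and 0.0726 with the block. DECR1, the 2,4-dienoyl-CoA reductase (0.79, adjusted p = 0.0312), and ETFDH, which passes electrons to ubiquinone (0.55, adjusted p = 0.0396, and 0.0524 without a detection filter), rose over all genes tested, and 11 members adjusted over the list alone.

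In the respiratory chain, all 23 tested members of complexes II to IV with cytochrome c lay above 0, with a median of 0.33 (camera adjusted p = 1.09e-16; adjusted p = 0.148 with an estimated correlation; fry adjusted p = 0.0166). COX7B of cytochrome c oxidase (0.84, adjusted p = 0.0438, and 0.0549 without a detection filter) and cytochrome c itself, CYCS (0.83, adjusted p = 0.0291), rose over all genes tested, and 15 members adjusted over the list alone. With the replicate block 6 rose. All 34 complex I members lay above 0 as well, with a median of 0.21 (camera adjusted p = 1.44e-13; adjusted p = 0.222 with an estimated correlation; fry adjusted p = 0.0166). Here 3 rose over all genes tested and 11 adjusted over the list alone: NDUFB9 was at 0.88 (adjusted p = 0.0291), COXFA4, listed here under its older name NDUFA4, at 0.83 (adjusted p = 0.0221) and NDUFB10 at 0.62 (adjusted p = 0.0312). COXFA4 is now counted as a subunit of cytochrome c oxidase, so of these 3 only NDUFB9 and NDUFB10 belong to complex I. For ATP synthase the median was 0.25 with 15 of 17 members above 0 (camera adjusted p = 3.04e-08; adjusted p = 0.224 with an estimated correlation; fry adjusted p = 0.0377). No member passed over all genes tested and 11 did adjusted over the list alone. ATP5F1C, the gamma subunit, was at 0.75 (adjusted p = 0.076, and 0.037 with the block) and ATP5MC3 at 0.47 (adjusted p = 0.165, and 0.0435 with the block).

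Smaller shifts were found in other mitochondrial lists. Branched chain amino acid and ketone catabolism had a median of 0.16 (camera adjusted p = 0.0004; adjusted p = 0.224 with an estimated correlation), or 0.10 without no-doxycycline replicate 1 (adjusted p = 0.0175). MCCC1 of leucine breakdown rose (0.75, adjusted p = 0.0312), and 2 members passed adjusted over the list alone, or 7 with the block, where 2 passed over all genes tested. Respiratory chain assembly factors had a median of 0.11 (camera adjusted p = 0.000298; adjusted p = 0.224 with an estimated correlation; fry adjusted p = 0.0747, and 0.0351 with the block). No member passed over all genes tested and 1 adjusted over the list alone, or 2 and 6 with the block. UQCC1 was at 0.53 (adjusted p = 0.0665, and 0.041 with the block) and NDUFAF4 at 0.44 (adjusted p = 0.175, and 0.0485 with the block). Among 74 mitochondrial ribosome genes the median was 0.08 with 57 above 0 (camera adjusted p = 6.88e-07; adjusted p = 0.361 with an estimated correlation; fry adjusted p = 0.113, and 0.0351 with the block). None passed over all genes tested and 1 adjusted over the list alone, or 1 and 3 with the block. MRPL48 was at 0.52 (adjusted p = 0.11) and MRPL41 at 0.45 (adjusted p = 0.0502, and 0.0445 with the block).

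Mitochondrial dynamics and mitophagy had a median of 0.15 (camera adjusted p = 0.0112; adjusted p = 0.224 with an estimated correlation), with PINK1 at 0.39 (adjusted p = 0.382) and BNIP3L at -0.35 (adjusted p = 0.415). Its call was lost without no-doxycycline replicate 1 (adjusted p = 0.0588) or doxycycline replicate 2 (adjusted p = 0.0526). Mitochondrial import and chaperones had a median of 0.09 (camera adjusted p = 0.00553; adjusted p = 0.627 with an estimated correlation), and the call was lost without doxycycline replicate 1 (median 0.05, adjusted p = 0.143). TIMM8A was at 0.46 (adjusted p = 0.133) and HSPD1 at 0.30 (adjusted p = 0.266), the latter with probes that disagreed in sign. Neither list had a member past the threshold over all genes tested or adjusted over the list alone. Mitochondrial DNA maintenance and transcription did not pass (median 0.01, camera adjusted p = 0.0938), although its member ENDOG, a mitochondrial nuclease, rose (0.89, adjusted p = 0.029). That list passed upward with array weights (median 0.07, adjusted p = 0.0422) and without doxycycline replicate 2, the array that stands apart (median 0.10, adjusted p = 0.0178). ENDOG was also its 1 call adjusted over the list alone.

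**Figure D3:**
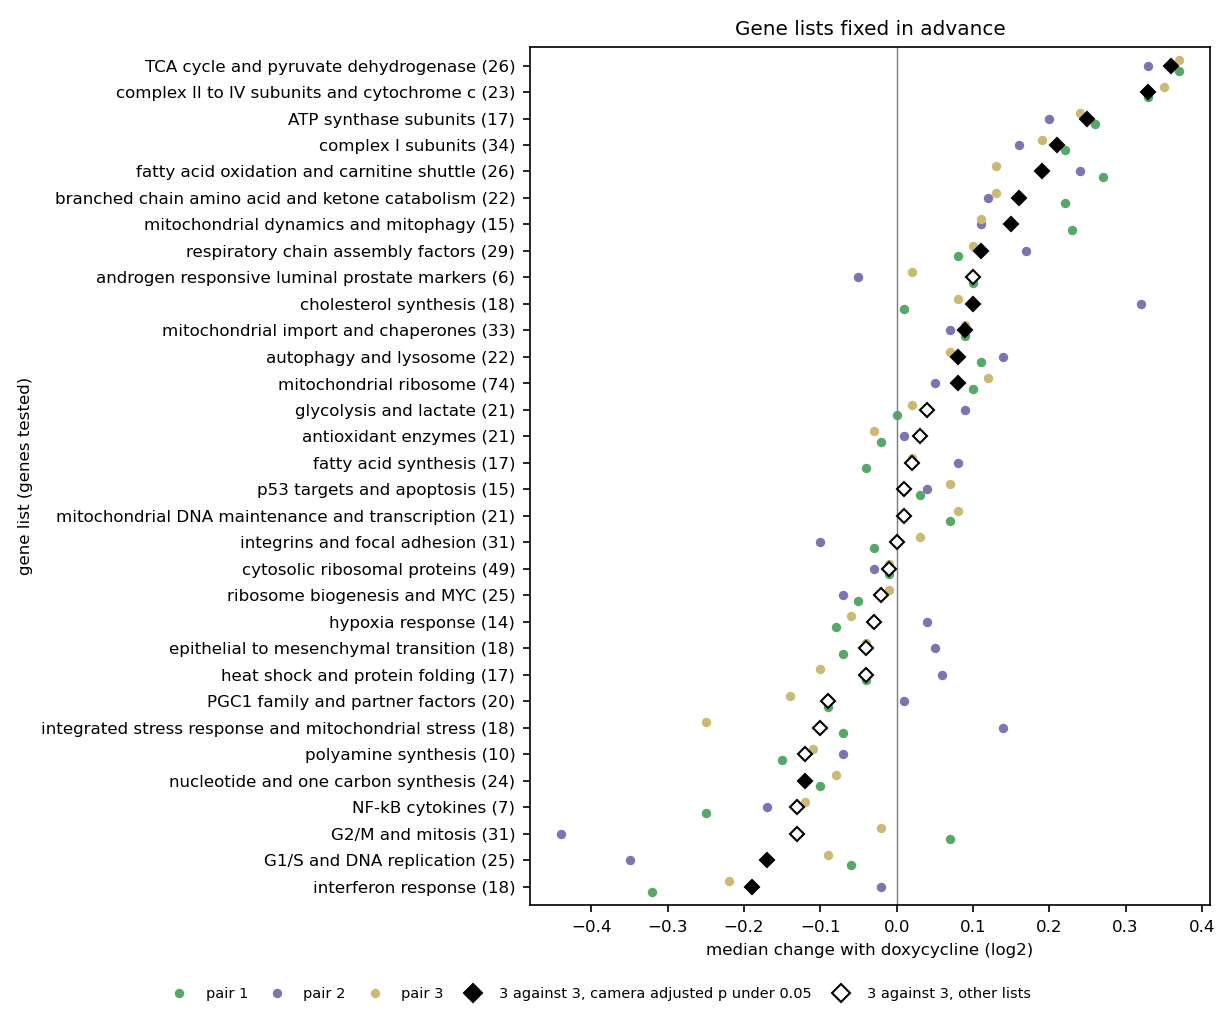
Median log2 change with doxycycline (x axis) of the lists reported (y axis, with the genes tested in each). Diamonds are the medians of the change between groups, filled where camera's adjusted p was under 0.05; circles are the medians of the differences between arrays of the same replicate number. The TCA cycle list lies highest at 0.36 with its pairs at 0.37, 0.33 and 0.37, while pair 2 of the G2/M list lies apart at -0.44.

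Outside the mitochondrion, 2 further lists passed upward with the preset correlation. Autophagy and lysosome had a median of 0.08 (camera adjusted p = 0.0182; adjusted p = 0.361 with an estimated correlation). WIPI1, an autophagosome factor, was at 0.94 (adjusted p = 0.102, and 0.0164 with the block) and GABARAPL1 at 0.49 (adjusted p = 0.298). No member passed over all genes tested and 2 did adjusted over the list alone, or 4 with the block. The 2 were WIPI1 and CTSA, the latter named after its value was seen (0.36, adjusted p = 0.125). Cholesterol synthesis had a median of 0.10 (camera adjusted p = 0.0165; adjusted p = 0.712 with an estimated correlation). CYP51A1 was not above background without doxycycline and at least 1.17-fold higher with it (adjusted p = 0.113), and MSMO1 was at 0.43 (adjusted p = 0.266). No member passed over all genes tested and 1 did adjusted over the list alone, or 3 with the block. Without doxycycline replicate 2 the adjusted p was 0.883 for cholesterol synthesis, with a median of -0.05, and 0.121 for autophagy, with a median of 0.04. Without no-doxycycline replicate 1 these were 0.182 and 0.085, and with array weights 0.162 and 0.0838. The cholesterol median was 0.04 and 0.05 in these fits, 0.20 without no-doxycycline replicate 2 (adjusted p = 0.000875) and 0.25 without doxycycline replicate 1 (adjusted p = 3.6e-05). The cholesterol call was also lost with probes detected on all 6 arrays (adjusted p = 0.0795).

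The 3 lists that passed downward with the preset correlation were nucleotide and one carbon synthesis, G1/S and DNA replication, and the interferon response. Nucleotide and one carbon synthesis had a median of -0.12 with 20 of 24 members below 0 (camera adjusted p = 0.00553; adjusted p = 0.222 with an estimated correlation; fry adjusted p = 0.0747, and 0.0168 with the block). PHGDH, the entry enzyme of serine synthesis, was at -0.50 (adjusted p = 0.237) and the ribonucleotide reductase subunit RRM2 at -0.39 (adjusted p = 0.516). The camera adjusted p was 0.0526 without doxycycline replicate 2. G1/S and DNA replication had a median of -0.17 with 21 of 25 members below 0 (camera adjusted p = 0.0163; adjusted p = 0.712 with an estimated correlation). UHRF1 was at -0.36 (adjusted p = 0.458) and PCNA at 0.33 (adjusted p = 0.412), the latter with probes that disagreed in sign. Pair medians were -0.06, -0.35 and -0.09, and the call was lost without doxycycline replicate 2 (median -0.08, adjusted p = 0.816) or no-doxycycline replicate 1 (-0.15, adjusted p = 0.161), and with array weights (-0.11, adjusted p = 0.125). The G1/S median was -0.28 without doxycycline replicate 1 (adjusted p = 4.7e-05). Neither list had a member past the threshold over all genes tested or adjusted over the list alone, except 1 of the nucleotide list adjusted over the list alone with the block.

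G2/M and mitosis did not pass in the full comparison (median -0.13, camera adjusted p = 0.119), with pair medians of 0.07, -0.44 and -0.02. Without doxycycline replicate 2 its median was 0.08 and it passed in the upward direction (adjusted p = 0.0271). It passed downward without no-doxycycline replicate 2 (median -0.18, adjusted p = 0.0201), doxycycline replicate 1 (-0.26, adjusted p = 0.000213) or doxycycline replicate 3 (-0.21, adjusted p = 0.00507). CDK1 was at 0.29 (adjusted p = 0.633), with probes that disagreed in sign, and PLK1 at -0.28 (adjusted p = 0.524).

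The interferon response had a median of -0.19 with 15 of 18 members below 0 (camera adjusted p = 0.0376; adjusted p = 0.684 with an estimated correlation). IFI44L fell over all genes tested, and 2 members passed adjusted over the list alone, 1 in each direction, or 8 with the block. The call was lost under 11 of 15 other settings, among them without no-doxycycline replicate 1 (adjusted p = 0.161) or 2 (0.0664) and without doxycycline replicate 1 (0.129) or 3 (0.369, median -0.12). Without doxycycline replicate 2 the median was -0.30 (adjusted p = 0.000914). The other losses, with all 6 arrays kept, had adjusted p from 0.052 to 0.0814.

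Among the lists that did not pass, glycolysis and lactate had a median of 0.04 (camera adjusted p = 0.27). LDHB, the lactate dehydrogenase subunit of oxidative tissues, rose (0.52, adjusted p = 0.0438, but 0.0629 with median scaling and 0.0575 without a detection filter), and 3 members passed adjusted over the list alone, or 6 with the block. With the block the enolase ENO2 also passed over all genes tested, but as a fall (-0.45, adjusted p = 0.0474). The PGC1 family and partner factors had a median of -0.09 (camera adjusted p = 0.282), with ESRRA as the 1 member past the threshold adjusted over the list alone and MEF2C at 0.39 (adjusted p = 0.415). NF-kB cytokines had a median of -0.13 over 7 genes (camera adjusted p = 0.717). IL32 in that list rose: it was not above background without doxycycline and at least 1.08-fold higher with it (adjusted p = 0.0312; log2 0.49 without background correction, adjusted p = 0.0241; adjusted p = 0.211 without a detection filter), the 1 call adjusted over the list alone, or 2 with the block. Fatty acid synthesis had a median of 0.02 (camera adjusted p = 0.275, and 0.021 without doxycycline replicate 1), with ACACB at 0.90 (adjusted p = 0.076, and 0.0462 with the block) and ME1 at 0.46 (adjusted p = 0.0811) as its 2 calls adjusted over the list alone. Integrins and focal adhesion had a median of 0 to 2 decimals (camera adjusted p = 0.544). Its 2 calls adjusted over the list alone were the integrin ITGA5 at -0.61 (adjusted p = 0.0934, and 0.0271 with the block) and the collagen COL13A1 at -0.53 (adjusted p = 0.118, and 0.0457 with the block). With the block 4 members passed adjusted over the list alone.

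The stress list, which joins the integrated and mitochondrial stress responses, had a median of -0.10 (camera adjusted p = 0.638, and 0.0185 with a median of -0.26 without doxycycline replicate 2), with ASNS at -0.33 (adjusted p = 0.537) and DDIT3 at 0.31 (adjusted p = 0.432). Antioxidant enzymes had a median of 0.03 (camera adjusted p = 0.732), with SOD2 at 0.41 (adjusted p = 0.148) and TXN2 at -0.31 (adjusted p = 0.56). Polyamine synthesis had a median of -0.12 (0.277), with SAT1 at 0.27 (adjusted p = 0.547) and SRM at -0.21 (adjusted p = 0.42). For heat shock and protein folding the median was -0.04 (0.79), with HSPA1A at 0.44 (adjusted p = 0.382) and HSP90AB1 at -0.19 (adjusted p = 0.342). For hypoxia it was -0.03 (0.79), with HIF1A at 0.35 (adjusted p = 0.317) and HILPDA at -0.34 (adjusted p = 0.166). Ribosome biogenesis and MYC had a median of -0.02 (0.768), with NOLC1 at -0.23 (adjusted p = 0.238) and DKC1 at -0.18 (adjusted p = 0.321). Cytosolic ribosomal proteins were at -0.01 (0.732), with RPL8 at -0.56 (adjusted p = 0.219), whose probes disagreed in sign, and RPS28 at 0.46 (adjusted p = 0.129). No member of these lists passed over all genes tested or adjusted over the list alone. The p53 and apoptosis list had a median of 0.01 (0.582), with BCL2L1 at 0.39 (adjusted p = 0.159) and PMAIP1 at 0.35 (adjusted p = 0.415). Adjusted over the list alone 2 members passed, 1 in each direction: BCL2L1 and BAX. BAX, named after its value was seen, was at -0.32 (adjusted p = 0.15). Epithelial to mesenchymal transition had a median of -0.04 with camera's direction up (0.964; PLAUR at -0.43, adjusted p = 0.361, and CDH1 at -0.34, adjusted p = 0.658). It had 0 members past the threshold adjusted over the list alone, and 4 with the block.

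Markers of other cell types did not pass either. The 6 tested androgen-responsive luminal prostate markers had a median of 0.10 (camera adjusted p = 0.857), with TRPM8 at 0.32 (adjusted p = 0.609) and SLC45A3 at -0.23 (adjusted p = 0.299). The other marker lists had 4 tested genes or fewer, too few for the list test, and no member passed over all genes tested. PDGFRA was at -0.40 (adjusted p = 0.325) and LUM at 0.33 (adjusted p = 0.19) among fibroblast markers, where LUM passed adjusted over the list alone, or 2 members with the block. Blood markers CD14 and PPBP were at -0.31 (adjusted p = 0.339) and -0.30 (adjusted p = 0.335). Endothelial markers PECAM1 and ESAM were at -0.41 (adjusted p = 0.517) and 0.38 (adjusted p = 0.336), and 1 passed adjusted over the list alone with the block. Among muscle, neuronal and neuroendocrine markers ENO2 was at -0.45 (adjusted p = 0.282, and 0.0474 with the block) and SCG2 at 0.13 (adjusted p = 0.583). TRPM8, CD14, PPBP, PECAM1 and SCG2 lay close to background and were not detected on every array, so their changes are uncertain.

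At the level of probes, named or not, 106 of 15542 passed, 89 higher and 17 lower, and 167 passed with the replicate block. This count was 10, 4 and 1 without no-doxycycline replicates 1, 2 and 3, and 6, 26 and 9 without doxycycline replicates 1, 2 and 3.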

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

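The tests of the PPARGC1A probe and of doxycycline replicate 2 were chosen after those results were seen; the tests of the respiratory chain lists were not. Of 2900 tested probes without a gene name here, 26 passed the threshold, 25 higher and 1 lower with doxycycline, and 38 passed with the replicate block. They are flagged because the comparisons of genes leave them out. The largest rise was in ILMN_2407824, from 9.16 to 10.76 (log2 1.60, SE 0.118, adjusted p = 0.00396), and the only fall was in ILMN_1680208, by 0.68 (adjusted p = 0.0407).

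The 74 respiratory chain and ATP synthase genes had a joint median log2 change of 0.24, with 72 of them above 0. A dependence of the change on brightness is argued against, since 0 of 10000 brightness-matched random lists had a median as high, and the central 95% of them ended at 0.032. Background subtraction is argued against as the source of this joint median too, since without it the median kept 98.0% of its value. These lists are bright, with mean levels of 10.56, 10.63 and 11.33 log2, where subtraction changes little. The test therefore does not cover dim members such as NDUFB9 and CYCS, at 6.43 and 6.66 without doxycycline. An effect of doxycycline itself, which blocks mitochondrial translation at some doses, stays open: the stress list that such a block would raise had a median of -0.1 with a camera adjusted p of 0.638 (-0.26 and 0.0185 without doxycycline replicate 2), and no treated cells without the construct were analysed here. Induced PGC1A and doxycycline therefore cannot be told apart for this pattern.

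The PPARGC1A probe was at a similar level in both groups. Exchanged group labels are argued against by ESRRA, which lay higher in the arrays labelled doxycycline by 6.16 standard errors, as far as ESRRA follows PGC1A. This evidence is limited, since the test was set after the results were seen. The limma adjusted p of ESRRA was 0.0502, just over the threshold, and from 0.092 to 0.205 with 1 array left out. That the probe does not read the construct's transcript stays open, because the probe's change of 0.168 standard errors is what that explanation needs but is also what an absent induction would give. The sequences of the probe and the construct, which would decide it, were not analysed here.

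The proliferation lists were lowest in doxycycline replicate 2 against its pair. Over the 56 G1/S and G2/M genes the median difference was -0.38 in pair 2, with 51 genes lower, against 0.02 with 26 lower in pair 1 and -0.04 with 38 lower in pair 3; the G1/S list alone lay below 0 in all 3 pairs. A brightness-dependent normalization of that pair is argued against, since the median lay at percentile 0.0 of matched lists, whose central 95% began at -0.083. Poor array quality stays open: the 15437 probes detected on that array lie inside the range of the other 5, which excludes nothing. The pattern may not belong to that array alone. Among the arrays without doxycycline, UHRF1, CDK1 and PLK1 were also lowest in replicate 2, at 12.05, 7.84 and 8.14, while PCNA was not. In doxycycline replicate 2 these 3 genes were at 11.43, 7.75 and 7.63, the lowest of that group. A culture that differed in growth state may be the source, and no biological explanation was tested.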

How the results depend on the processing

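Leaving out pair 2 was chosen after the arrays were seen; all other settings were planned. In the counts of genes past the threshold, 53 became 81 without background correction, 81 on the deposited table, 30 without a detection filter, 177 with the replicate block, 207 with array weights, 101 with a variance trend and robust eBayes, 1 at adjusted p under 0.01, 1 (ECM1) without pair 2 and 1 to 9 when an array was left out. Leaving out an array leaves fewer samples, and 43 of the 53 genes passed in none of these 6 fits, although all 53 kept their direction in all 6. For probes past the threshold, 106 became 198, 198, 6, 167, 255 and 240 under the same first 6 settings, 4 at adjusted p under 0.01, 2 without pair 2 and 1 to 26 when an array was left out. Without a filter every probe on the array was tested; for the other changes the cause was not tested.

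Of the gene lists, 15 past the threshold became 0 with an estimated correlation, 5 by fry, 0 with the replicate block and an estimated correlation, and 7 with the block by fry. Without pair 2, 14 lists passed. With camera's preset correlation 8 of the 15 calls held under all 15 planned settings: complex I, complex II to IV, ATP synthase, assembly factors, the TCA cycle, fatty acid oxidation, branched chain amino acids and the mitochondrial ribosome. The other 7 were lost under at least 1. The median of G2/M and mitosis ranged from -0.26 to 0.08 when an array was left out. Among results not past the threshold, 4 of 61 named genes and 10 of 18 lists changed sign under some setting.

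ESRRA passed under 7 of 15 settings, with adjusted p from 0.0246 to 0.205: 0.44 without background correction, 0.44 on the deposited table, 0.50 with probes detected on all 6 arrays, 0.50 for the mean of probes, 0.50 with the replicate block, 0.46 with array weights and 0.50 with the variance trend. PPARGC1A was at -0.19 with array weights and between -0.16 and 0.17 when an array was left out. MYC was at 0.20 for the mean of probes, whose probes disagree, and between -0.19 and 0.08 when an array was left out. Among the genes named by the rule and the list tests, the block changed no other call than those given beside the results; other list members it moved past the threshold are in the counts there. Signal over background limits genes that were not above it in 1 group (TELO2, CEACAM21, IL32 and CYP51A1), which have only a bound. Of the 53 calls, 23 were lost without a detection filter, 4 without background correction, 4 on the deposited table, 4 for the mean of probes, 4 with a variance trend and 2 with median scaling. CEACAM21 was lost under 4 of these (adjusted p from 0.0133 to 0.192 over its settings); the cause was not tested.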

Other observations

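Of the 53 genes past the threshold, 38 were in none of the lists, and those described here were chosen after their values were seen. FASTKD1, a regulator of mitochondrial RNA, rose by 0.74 (SE 0.0877, adjusted p = 0.0291). NNT, the transhydrogenase of the inner mitochondrial membrane that supplies NADPH, rose by 0.62 (SE 0.085, adjusted p = 0.0327). SFXN4, an inner membrane protein needed for complex I assembly, rose by 0.49 (SE 0.0757, adjusted p = 0.0438) and MTFR1L, a mitochondrial fission regulator, by 0.74 (SE 0.105, adjusted p = 0.0388). METRNL, a secreted protein of the meteorin family, rose by 0.67 (SE 0.0876, adjusted p = 0.0312), and FUT8, the core fucosyltransferase, by 0.89 (SE 0.119, adjusted p = 0.0327), or by 0.52 without background correction (adjusted p = 0.0277). None of these 6 passed in any fit with 1 array left out. SFXN4 also lost its call with median scaling (adjusted p = 0.0553) and without a detection filter (0.0575), and METRNL for the mean of its probes (0.47, adjusted p = 0.0753).

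Glutathione transferases were looked at because members stood among the calls, so their number was not tested against chance. Of 14 tested members 4 rose: GSTM1 at 0.99, GSTM4 at 0.88 (adjusted p = 0.0438, and 0.49 without background correction, adjusted p = 0.0356), MGST3 at 0.59 (adjusted p = 0.0438) and GSTK1 at 0.52 (adjusted p = 0.0462). None of the 4 passed in any of the 6 fits with 1 array left out, and without a detection filter GSTM4 and MGST3 (adjusted p = 0.0557 each) and GSTK1 (0.0603) lost their calls. GSTM1 and GSTM4 are closely related in sequence, and whether their probes read each other's transcripts was not analysed here. The other members did not pass and ranged from MGST2 at 0.34 (adjusted p = 0.19) and GSTZ1 at 0.25 (adjusted p = 0.245) to GSTP1 at -0.09 (adjusted p = 0.706) and GSTT2 at -0.10 (adjusted p = 0.641).

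The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 53 genes past the threshold and the highest other 0, and for probes 106 against 0. For gene lists with camera's preset correlation the real split gave 15 and the highest other 13. In each case no other split gave as many as the real one. By fry the real split gave 5 lists and the highest other 1. The 3 other splits that part all 3 pairs, as the real one does, each gave 0 genes, with 10, 10 and 5 lists by camera's preset correlation. Every other split gave at least 5 lists by that test. The other splits mix the groups unevenly, so they keep part of the real difference and add the rest to the spread. Their counts are therefore no measure of chance alone, and the added spread favours a count of 0 genes.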
